A study of Mus musculus with 6 samples.

How the data were processed

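RNA from the proximal incisor of 6 mice was sequenced, 3 of the control genotype Runx2fl/fl and 3 of the genotype Gli1-CreERT2;Runx2fl/fl, called cKO. Per the labels' protocols, mice received tamoxifen in corn oil (20 mg/ml) intraperitoneally at 1.5 mg per 10 g body weight. Every RNA sample had an RNA integrity number above 9.0, and single-end reads of 75 cycles were made on a NextSeq500. The labels give each mouse its own number, so replicates are separate animals. They are numbered here in accession order, which pairs no cKO mouse with a control. The protocol mentions pairs of samples without saying which belong together, so any such pairing is ignored by the unpaired test. The labels do not state the sex of the mice, a sequencing batch or whether the library kit kept strand.

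The submitters' processing notes name STAR 2.6.1d, Partek and the genome build mm10, with no parameters. The annotation release, the counting settings and the handling of reads that match several genes are not given in the sources used here. The deposited estimated counts cover 25700 genes, and only 45.6% to 48.0% of the values of a library were whole (tolerance 1e-09), as happens when a read is shared between features. Such sharing can add reads: the pseudogene Gm10925 held at least 99.9% as many counts as the mitochondrial gene mt-Atp6. No row lacked a gene name. A second deposited table holds a normalized signal for 20676 genes. Comparison with the counts showed that each value was the estimated count plus 1, multiplied by 1 factor per library (100% of values within 0.1%), with the 75th percentile at 41.5 to 41.6 in every library, so the authors' normalization was upper-quartile scaling. The 5024 genes left out of that table had at most 10 counts in any library. It holds no fold changes or p-values.

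Estimated counts were rounded to whole numbers. Genes were filtered with filterByExpr (minimum count 10, minimum total 15), which left 19264, and libraries were scaled by TMM. The main test was edgeR 4.0.16's quasi-likelihood F-test with default settings in R 4.3.3 on all 6 libraries without covariates, two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. The prior degrees of freedom were 3.12 and the common biological coefficient of variation was 0.153. Standard errors were taken from the fold change and its F statistic. CPM (counts-per-million) values use TMM-scaled library sizes, given as mean ± SD over 3 mice. Total counts ranged from 53525185 to 66694240, at which 1 count is worth 0.0150 to 0.0187 CPM. The 95% Clopper-Pearson intervals given for genes of few counts cover counting error only.

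Replicates were compared before use, only to find libraries that repeat 1 sample. The chi-square per degree of freedom over genes ran from 50.8 to 80.8 for the 6 pairs within groups, so none was counted as a repeat. At this depth separate animals exceed counting noise, so the values do not measure replicate quality. No column belonged to a sample outside the series.

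Before the data were examined, 33 gene lists were written down. Of these, 32 were tested with camera from limma 3.58.1 (preset correlation 0.01, lists with at least 3 tested members, Benjamini-Hochberg over the lists), and the list of sex-specific genes was used only to read the sex of each mouse. Of 651 listed genes, 601 were tested in the 32 lists, and 15 genes stand in more than 1 list. Counts adjusted over the list alone apply Benjamini-Hochberg to the members only. The rule for named genes was also set before. It takes Runx2 and Gli1, and up to 8 genes per direction past the threshold with a mean of at least 1 CPM, groups that do not overlap and no predicted-gene name. It takes the 10 genes of lowest p where fewer than 10 pass. From each list it takes up to 4 members past the threshold, or otherwise the 2 of lowest p as values. It takes Igf1, Igf2, Igf1r and Igfbp3, and Xist and Ddx3y as values per mouse. Krt6b, Hddc3, late enamel genes and the genes named only in the closing section were chosen after their values were seen.

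Coordinates are those of the deposited table in mm10, with the end reduced by 1 because the table gives the position after the last base. Genes sharing exonic sequence were read from GENCODE M21 on the same assembly, which need not be the annotation the authors counted with. Of the 76 named genes, 27 share exonic bases with another gene. Because strand is not stated, reads of a gene and its antisense partner cannot be told apart. Among the named genes the largest shares are those of Sp6 with Gm11532 (86.7%), Igf2 with Gm49394 on the same strand (62.8%), Gm18310 with Hddc3 (62.7%) and Gpat3 with 4930458D05Rik (30.0%).

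The scripts were tested on simulated data. Counts were drawn for 18989 genes, 200 of them changed, with the means and library sizes of this comparison. From these edgeR recovered 87% of genes changed by 1 on the log2 scale and 99% of those changed by 2. It made 13 false calls among the unchanged. DESeq2 1.42.0 recovered 96% and 99%, with 69 false calls, and limma-voom 87% and 99%, with 14. With 20 simulated lists, 10 of them shifted by 0.5 on the log2 scale over 19264 genes, camera with either correlation and fry each found all 10 and called none of the others. Genes were drawn independently of each other, so this does not test the preset correlation. Counts were drawn from the fitted dispersions alone, so the recovered shares do not measure power in the real data. There, of the 20 DESeq2 genes in the closing section, all changed by over 2 on the log2 scale, edgeR called Eda2r alone.

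The alternatives set beforehand were DESeq2 size factors, library size alone, no filter on low counts, a filter of at least 1 CPM in at least 3 libraries, DESeq2, limma-voom, adjusted p under 0.01, an added threshold of 1 on the log2 scale, sex as a covariate, each library left out in turn, and, for the lists, camera with an estimated correlation, camera on ranks and fry. Added after seeing the data were upper-quartile scaling, limma-trend on the deposited normalized signal, adjusted p under 0.1 and a covariate of late enamel genes (mean log2 CPM of Klk4, Amtn, Odam, Odaph, Slc24a4 and Wdr72).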

Results

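RNA was measured by sequencing in the proximal part of the incisor, the end at which the continuously growing mouse incisor keeps its stem cells. The labels call the tissue dental mesenchyme. The animals were 5-week-old C57BL/6 mice of 2 genotypes, with 3 mice in each group. Control mice carried a floxed Runx2 gene (Runx2fl/fl) without Cre. In the conditional knockout (cKO) mice, Gli1-CreERT2;Runx2fl/fl, tamoxifen activates a Cre recombinase in cells that express Gli1, a hedgehog pathway transcription factor that marks the mesenchymal stem cells of the incisor. Tamoxifen was given on 3 consecutive days at 1 month of age, and tissue was taken 1 week after induction. The estimated counts added up to 53525185, 66694240 and 59709715 for control 1 to 3 and 66366749, 62415177 and 62820280 for cKO 1 to 3. The libraries also differed in ways unrelated to the labels. Control 1 was the 1 male, with an Xist level of 0.596 CPM (counts-per-million) and 4059 counts of the Y-linked gene Ddx3y. The 5 other mice were female, with Xist between 2870 and 3390 CPM and at most 1 count of Ddx3y. Sex therefore cannot be told apart from the mouse control 1. A sex covariate is not a check separate from leaving that mouse out.

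Runx2, the transcription factor of bone and tooth mesenchyme that was targeted, was lower in every cKO mouse than in every control. The question of the comparison was how loss of Runx2 from Gli1-expressing cells alters the transcriptome of the proximal incisor. Controls lacked Cre, so for every difference Runx2 loss cannot be told apart from an effect of the Gli1-CreERT2 allele or its activation. Runx2 (chromosome 17, 44495987 to 44814797, build mm10) measured 79.5 ± 1.72 CPM (SD, n = 3) in controls. In cKO mice it measured 62.6, 54.0 and 49.0 CPM, with a mean of 55.2 ± 6.88 (SD, n = 3). The log2 fold change was -0.53 (SE 0.089), a cKO level 0.694 times that of control. It did not pass the threshold over all genes (edgeR quasi-likelihood test, adjusted p = 0.0714). It passed with DESeq2 (adjusted p = 0.000126), and over the 16 alternatives the adjusted p ran up to 0.539. Counts cover the whole gene, so they include RNA from cells without Cre and RNA from parts of the gene outside the floxed segment. Gli1 (chromosome 10, 127329882 to 127341974) measured 159, 89.7 and 207 CPM in the controls and 75.0, 77.9 and 70.6 CPM in the cKO mice. Its log2 fold change of -1.03 (SE 0.27) did not pass either (edgeR adjusted p = 0.131). Gli1 passed without control 2 (log2 fold change -1.30, edgeR adjusted p = 0.0329) and with DESeq2 (adjusted p = 0.00183). With late enamel genes as a covariate the Gli1 difference was -0.35 (edgeR adjusted p = 0.690, the highest over its 16 alternatives).

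**Figure D1:**
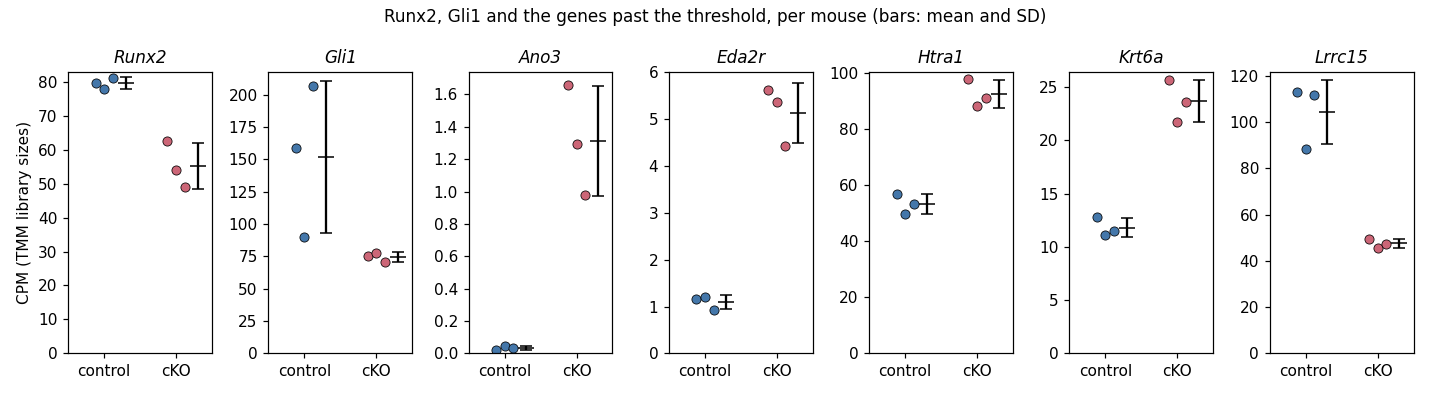
Expression in CPM (vertical axes, linear and starting at 0) of Runx2, Gli1 and the 5 genes past the threshold, with 1 point per mouse for the 3 control and 3 cKO mice and the mean with its SD beside the points. Runx2 lies between 77.7 and 81.2 CPM in controls and between 49.0 and 62.6 CPM in cKO mice, and Ano3 is near 0 in controls.

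Across the transcriptome 5 of 19264 tested genes changed, of which 4 rose and 1 fell in cKO mice (edgeR, adjusted p under 0.05). Eda2r, a receptor of the tumour necrosis factor family and a target of p53 (chromosome X, 97333840 to 97377216), rose 4.68-fold, from 1.10 ± 0.146 to 5.14 ± 0.634 CPM (SD, n = 3 each; edgeR adjusted p = 0.0302). Krt6a, a keratin of stressed and stratified epithelia (chromosome 15, 101689910 to 101694307), rose 2.01-fold, from 11.8 ± 0.916 to 23.7 ± 1.98 CPM (edgeR adjusted p = 0.0402). Htra1, a secreted serine protease that cleaves matrix proteins and IGF-binding proteins (chromosome 7, 130936111 to 130985660), rose 1.74-fold, from 53.2 ± 3.44 to 92.4 ± 4.98 CPM (edgeR adjusted p = 0.0385). Ano3, a membrane protein of the anoctamin family (chromosome 2, 110655201 to 110950923), had 1, 3 and 2 counts in the controls and 111, 81 and 61 in the cKO mice. The depth-scaled ratio of the Ano3 sums was 39.6, with a 95% Clopper-Pearson counting interval of 17.9 to 109 (edgeR adjusted p = 0.0302). Lrrc15, a membrane protein of mesenchymal cells (chromosome 16, 30269302 to 30283256), fell 2.20-fold, from 104 ± 13.8 to 47.5 ± 1.97 CPM (edgeR adjusted p = 0.0385).

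The 5 genes with the next lowest p did not pass (edgeR adjusted p = 0.0610 for each). The unclassified transcript Gm18310 (chromosome 7, 80344082 to 80347993) had 245 counts in the 3 controls together and 3 in the cKO mice, a ratio of 87 (95% counting interval 29.4 to 425). As much as 62.7% of its exonic sequence lies antisense to Hddc3, whose own mean was 19.9 CPM in controls and 26.5 CPM in cKO mice. Svop, a synaptic vesicle protein, had 13 and 141 counts, a ratio of 10.2 (5.77 to 19.6) toward cKO. Gpat3, an acyltransferase of glycerolipid synthesis, had a log2 fold change of -1.01, and the calcium channel subunit Cacna2d2 one of -0.81. Pop4, a subunit of ribonuclease P, had a log2 fold change of 0.73. Reads of Krt6a and the similar keratin Krt6b (0.154 and 1.21 CPM) are hard to separate, and Krt6a shares 19.5% of its exonic sequence with an antisense transcript. The count of 5 rested on the test and on single libraries. DESeq2 called 1333 genes (698 higher, 635 lower), all 5 among them, and edgeR called 0 without control 1, without cKO 1 or without cKO 2, 3 without control 3, 8 without cKO 3 and 72 without control 2. At an unadjusted edgeR p under 0.05 there were 3325 genes, and 3103, 3278 and 2700 in the fits that called 0, in which DESeq2 called 1291, 1105 and 897. The edgeR count was also 0 with sex or late enamel genes as a covariate (3073 and 1479 genes at unadjusted p under 0.05, and 1148 and 172 by DESeq2). The sex covariate sets only control 1 apart, so that fit largely repeats the one without control 1.

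Of 32 gene lists chosen before the data were examined, 18 shifted together, 12 toward higher and 6 toward lower expression in cKO mice (camera, preset correlation 0.01, adjusted p under 0.05). None of the 18 calls held with a correlation estimated from the data, where the lowest adjusted p was 0.290 and 4 lists had an unadjusted p under 0.05. Over the called lists the estimated correlation ran from -0.0205 (pericyte and smooth muscle genes) to 0.867 (skeletal muscle genes). By fry, 3 were called, namely macrophage, endothelial and immediate early genes. For each called list the estimated correlation gave the highest adjusted p of all alternatives, except pericyte and smooth muscle genes, where it was 0.516 with camera on ranks. The lowest adjusted p of the called lists over the alternatives lay between 3.5e-52 and 0.0106. Libraries that stood apart from their group bear on several lists. Late enamel genes, a set of 6 chosen after the libraries had been compared, were high in control 2 and in all cKO mice, with a mean log2 CPM 2.85 above the control mean in control 2 and 3.23, 2.44 and 2.12 above it in the cKO mice, against -1.29 and -1.56 in control 1 and control 3. Skeletal muscle genes were high in control 1 (2.97). Neutrophil and marrow genes were high in cKO 1 (3.58) and cKO 2 (2.72) but not in cKO 3 (-0.295).

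**Figure D2:**
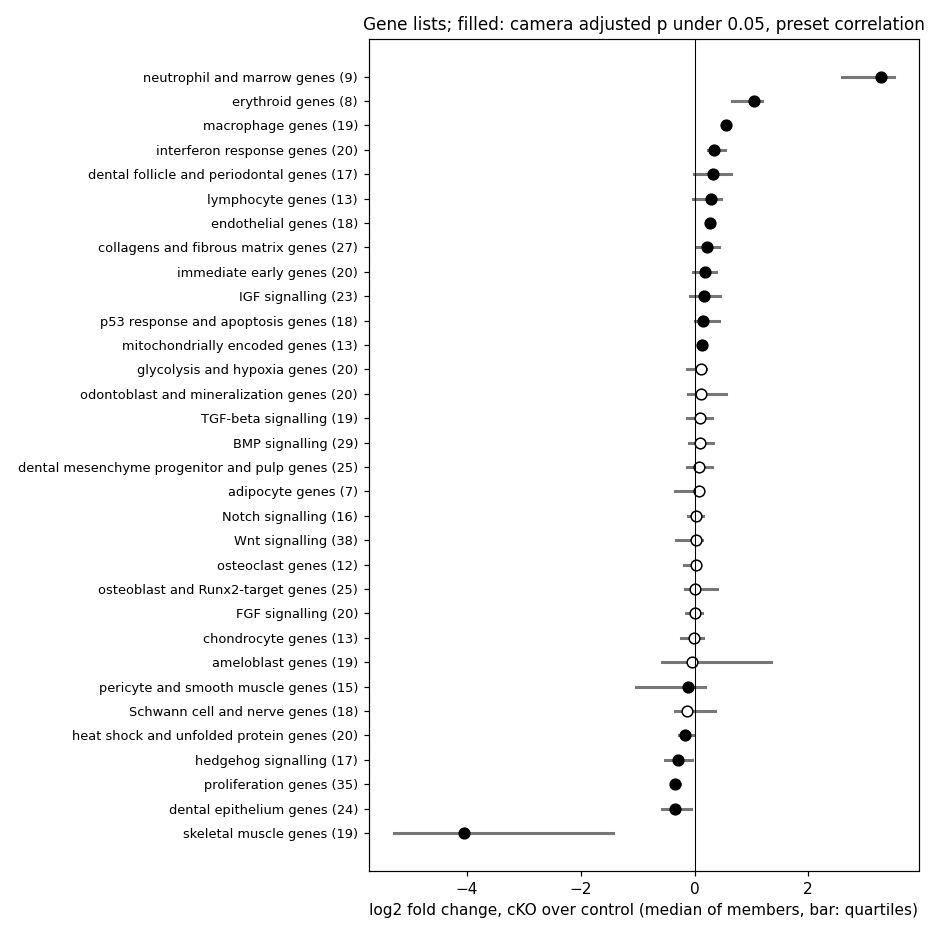
Median log2 fold change, cKO over control, of the tested members of each of the 32 gene lists (number of members in brackets), with bars from the lower to the upper quartile and filled points for the 18 lists called by camera with the preset correlation. Medians run from -4.05 for skeletal muscle genes to 3.28 for neutrophil and marrow genes, and macrophage genes stand at 0.558 with a narrow bar.

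Genes of IGF signalling were higher as a list in cKO mice, with 13 of 23 members above 0 and a median log2 fold change of 0.16 (camera adjusted p = 0.00412; adjusted p = 0.346 with an estimated correlation). Htra1 was the 1 member that rose over all genes tested, and 6 were higher and 0 lower when adjusted over the list alone. The ligands and the receptor gave no such call. Igf1 measured 369 ± 25.3 CPM in controls and 322 ± 104 CPM in cKO mice (log2 fold change -0.19, SE 0.23), and Igf2 472 ± 80.3 and 594 ± 73.9 CPM (0.33, SE 0.14). Igf1r had a log2 fold change of -0.059 (SE 0.10) and the binding protein Igfbp3 one of 0.39 (SE 0.18), and none of the 4 genes passed (edgeR adjusted p between 0.295 and 0.815). Igfbp3 was at 0.25 without cKO 1 and 0.57 without cKO 3. The direction of Igf1 turned without cKO 3 (0.043) and that of Igf1r without control 2 (0.043). The call of the list was lost without cKO 2 (median 0.145) and with camera on ranks. The median was 0.022, 0.069, 0.11 and 0.047 without control 1, control 2, control 3 or cKO 1, and 0.26 with no filter on low counts, 0.093 with a filter of 1 CPM and 0.017 with sex as a covariate. Genes of the p53 response and apoptosis were also higher as a list (median 0.14, 13 of 18 members above 0, camera adjusted p = 0.000118; adjusted p = 0.290 with an estimated correlation). Eda2r rose over all genes tested, and 6 members were higher and 0 lower adjusted over the list alone. With late enamel genes as a covariate the median was 0.23.

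Genes of hedgehog signalling were lower as a list in cKO mice, with 13 of 17 members below 0 and a median log2 fold change of -0.28 (camera adjusted p = 0.00316; adjusted p = 0.290 with an estimated correlation). No member passed over all genes tested, and 5 were lower and 1 higher adjusted over the list alone. Ptch1, the hedgehog receptor and a target of the pathway, measured 663 ± 34.9 CPM in controls and 462 ± 56.8 CPM in cKO mice (log2 fold change -0.52, edgeR adjusted p = 0.0878). The co-receptor Boc went the other way, from 23.0 ± 1.09 to 33.4 ± 1.48 CPM (0.54, edgeR adjusted p = 0.0610). The list median moved to -0.15 without control 3, -0.16 without cKO 3 and -0.18 with late enamel genes as a covariate. Proliferation genes were lower as a list, with 34 of 35 members below 0 and a median of -0.34 (camera adjusted p = 1.63e-09; adjusted p = 0.464 with an estimated correlation). No member passed either adjustment. The replication clamp Pcna measured 74.9 ± 7.29 and 61.1 ± 1.88 CPM, and the helicase subunit Mcm3 33.2 ± 5.09 and 24.9 ± 0.946 CPM. The groups overlapped, since the mean log2 CPM of proliferation genes in control 1 (-0.290 from the control mean) lay among the cKO values (-0.268, -0.293 and -0.322). Without control 3 the median was -0.20. Heat shock and unfolded protein genes were lower as a list (median -0.16, 15 of 20 members below 0, camera adjusted p = 0.0142; adjusted p = 0.661 with an estimated correlation). No member passed either adjustment. The endoplasmic reticulum proteins Manf and Hsp90b1 had log2 fold changes of -0.41 and -0.27. The groups overlapped for the heat shock list, whose mean in cKO 1 (0.00726) lay above those of control 1 (-0.0595) and control 2 (-0.142). The call was lost without control 3 (median -0.050), without cKO 2 (-0.14) and with late enamel genes as a covariate (-0.042), and without control 2 the median was -0.24.

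Lists of tooth and connective tissue genes went both ways. Dental follicle and periodontal genes were higher as a list (median 0.33, 12 of 17 members above 0, camera adjusted p = 0.0277; adjusted p = 0.373 with an estimated correlation). Adjusted over the list alone, 6 members were higher and 2 lower. The tendon and ligament regulator Mkx measured 34.7 ± 4.17 and 54.3 ± 5.96 CPM, while smooth muscle actin, Acta2, measured 145 ± 38.5 and 60.2 ± 8.18 CPM. The list mean in cKO 3 (-0.000468) lay below that of control 2 (0.0585). The call was lost without control 1, control 2, control 3 or cKO 1 (medians 0.35, 0.40, 0.25 and 0.26), with sex as a covariate (0.34) and with late enamel genes as a covariate (0.17). Collagens and fibrous matrix genes were higher as a list (median 0.23, 21 of 27 members above 0, camera adjusted p = 0.000522; adjusted p = 0.464 with an estimated correlation), with 6 higher and 2 lower adjusted over the list alone. The proteoglycan Bgn measured 641 ± 77.6 and 1149 ± 148 CPM and the matrix protein Tnn 176 ± 29.5 and 76.2 ± 18.0 CPM. The median was 0.14 without control 3 and 0.083, with the call lost, when late enamel genes were a covariate. The collagen list mean in cKO 2 (0.109) lay below that of control 2 (0.135). Dental epithelium genes were lower as a list (median -0.34, 19 of 24 members below 0, camera adjusted p = 0.00032; adjusted p = 0.552 with an estimated correlation), with 2 lower and 1 higher adjusted over the list alone. Sp6, a transcription factor of dental epithelium that shares 86.7% of its exonic sequence with an antisense transcript, measured 548 ± 108 and 306 ± 37.2 CPM, and Krt15 99.4 ± 6.63 and 167 ± 35.4 CPM. The call was lost without cKO 3 (median -0.20), and without control 3 the median was -0.22. The groups overlapped, since the list mean in cKO 1 (-0.0409) lay above those of control 1 (-0.14) and control 2 (-0.0775). Pericyte and smooth muscle genes were lower as a list by mean (-0.605) more than by median (-0.11), with 8 of 15 members below 0 (camera adjusted p = 0.00412; adjusted p = 0.290 with an estimated correlation). Adjusted over the list alone, 5 were lower and 2 higher. Acta2 and the contractile protein Cnn1, at 10.8 ± 3.19 and 1.47 ± 0.536 CPM (log2 fold change -2.87, edgeR adjusted p = 0.0610), had the lowest p. The median of this list was above 0 without cKO 3 (0.016) and with a filter of 1 CPM (0.0060), both with camera still calling the list lower, and without control 3 or cKO 1 it was -0.0065 and -0.069. With late enamel genes as a covariate it was -0.067.

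Lists of bone-forming, dentin-forming, enamel-forming and pulp cells were not called. Osteoblast and Runx2-target genes had a median of 0.0030, a mean of -0.027 and 13 of 25 members above 0 (camera adjusted p = 0.950). Adjusted over the list alone, 3 were higher and 2 lower. The collagenase Mmp13, a known Runx2 target, measured 293, 81.3 and 492 CPM in the controls and 33.4, 36.1 and 19.2 CPM in the cKO mice (log2 fold change -3.29, SE 0.62, edgeR adjusted p = 0.0831). Mmp13 was at -1.66 with late enamel genes as a covariate (edgeR adjusted p = 0.583, the highest over its alternatives), and it passed with DESeq2 and, by edgeR, without control 2 (-3.73). Omd measured 136 ± 28.6 and 76.1 ± 15.4 CPM. Odontoblast and mineralization genes had a median of 0.11 (camera adjusted p = 0.0836), with 5 higher and 4 lower adjusted over the list alone. Dmp1, a phosphoprotein of dentin and bone, measured 30.2 ± 13.5 and 136 ± 60.7 CPM (log2 fold change 2.17, edgeR adjusted p = 0.0878), and Klf4 76.9 ± 10.5 and 52.6 ± 4.68 CPM. Dental mesenchyme progenitor and pulp genes had a median of 0.083, a mean of -0.035 and 6 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.331). Cd24a measured 844 ± 120 and 388 ± 57.2 CPM and Vcam1 58.1 ± 7.59 and 95.9 ± 3.77 CPM (edgeR adjusted p = 0.0614 for each). Ameloblast genes, those of the enamel-forming cells, had a median of -0.038 and a mean of 0.28 (camera adjusted p = 0.791), with 2 higher and 5 lower adjusted over the list alone. Itgb6 measured 51.8 ± 6.87 and 27.9 ± 3.27 CPM. Without control 2, whose late enamel genes were high, camera called the ameloblast list higher, although its median was 0.0060. Odontoblast genes were called without cKO 2 (median 0.13) or with no filter (0.12), while their median was 0.032 without cKO 3, 0.0645 without cKO 1 and 0.070 with sex as a covariate. Progenitor genes were called without cKO 1 (0.29), while their median was 0.0032 without cKO 3, 0.0315 without cKO 2, 0.19 without control 1, 0.18 with sex as a covariate and 0.16 with late enamel genes as a covariate. These calls use the preset correlation. With an estimated correlation and all 6 libraries the adjusted p was 0.949 for ameloblast, 0.373 for odontoblast and 0.704 for progenitor genes.

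Immune and endothelial genes were higher in cKO mice as lists. All 19 macrophage genes lay above 0, with a median log2 fold change of 0.56 and quartiles of 0.50 and 0.60 (camera adjusted p = 3.73e-27; adjusted p = 0.290 with an estimated correlation). None passed over all genes tested, and all 19 were higher adjusted over the list alone. Tyrobp, a signalling adaptor of myeloid cells, measured 18.3 ± 0.669 and 26.5 ± 1.07 CPM, and Laptm5 36.0 ± 1.85 and 50.8 ± 1.53 CPM (edgeR adjusted p = 0.0610 for each). Endothelial genes were higher (median 0.27, 17 of 18 members above 0, camera adjusted p = 8.38e-08; adjusted p = 0.290 with an estimated correlation), with 12 higher and 1 lower adjusted over the list alone. Tie1 measured 48.8 ± 2.0 and 60.7 ± 2.49 CPM and Pecam1 94.4 ± 2.81 and 113 ± 3.31 CPM. Interferon response genes were higher in all 20 members (median 0.35, camera adjusted p = 6.2e-07; adjusted p = 0.377 with an estimated correlation), with none passing either adjustment. The interferon-induced genes Oas1a and Usp18 had log2 fold changes of 0.53 and 0.42, and the list mean in cKO 3 (0.108) lay below that of control 1 (0.142). Immediate early genes were higher (median 0.19, 14 of 20 members above 0, camera adjusted p = 0.0142; adjusted p = 0.290 with an estimated correlation), with 2 higher adjusted over the list alone. Klf2 and Egr3 had log2 fold changes of 0.44 and 0.89, and the call was lost without cKO 1 (median 0.20) and with late enamel genes as a covariate (0.14). With a filter of 1 CPM the median was 0.11.

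**Figure D3:**
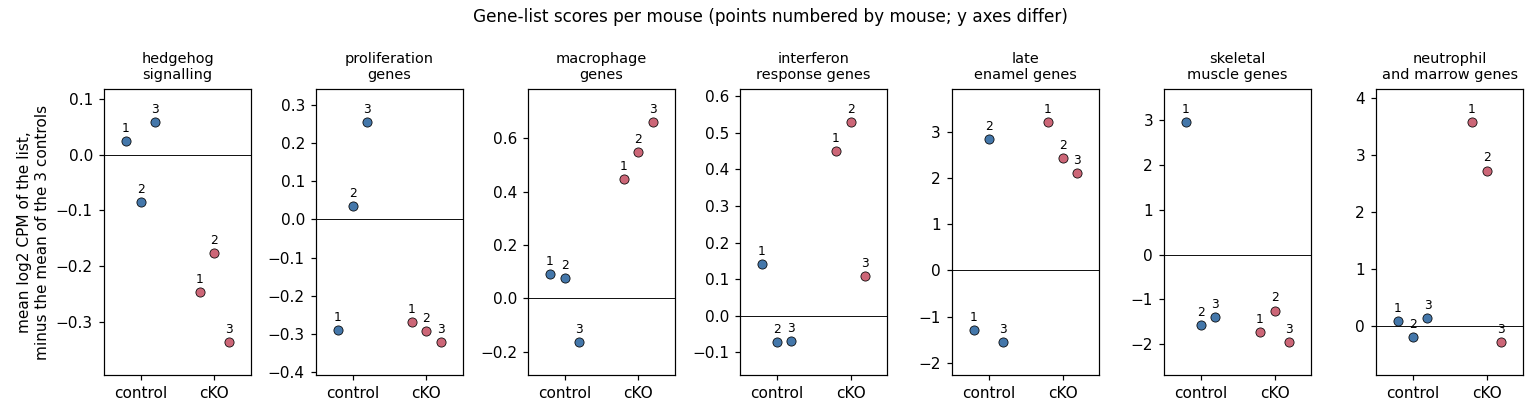
Mean log2 CPM of the members of 7 gene lists in each mouse, as the difference from the mean of the 3 controls (vertical axes, which differ between panels), with points numbered by mouse. Macrophage genes are between 0.446 and 0.662 in cKO mice and at most 0.0894 in controls, while late enamel genes set control 2 with the cKO mice, skeletal muscle genes set control 1 apart and neutrophil and marrow genes set cKO 1 and cKO 2 apart.

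Neutrophil and marrow genes were higher as a list (median 3.28, 9 of 9 members above 0, camera adjusted p = 5.38e-05; adjusted p = 0.377 with an estimated correlation), with 7 higher adjusted over the list alone. The difference stood in 2 of the 3 cKO mice. The neutrophil protein S100a8 measured 11.99 and 4.02 CPM in cKO 1 and cKO 2, 0.801 CPM in cKO 3 and at most 0.811 CPM in controls, and S100a9 measured 17.5, 6.08 and 1.17 CPM in cKO mice and at most 0.946 CPM in controls. Without cKO 1 the list median was 2.11. Erythroid genes were higher (median 1.05, 6 of 8 members above 0, camera adjusted p = 0.00191; adjusted p = 0.290 with an estimated correlation), with 2 higher adjusted over the list alone. The heme enzyme Alas2 measured 0.623 ± 0.239 and 1.39 ± 0.440 CPM and Slc4a1 0.0287 ± 0.0349 and 0.305 ± 0.106 CPM. The erythroid median was 0.63 without cKO 2, and the call was lost with a filter of 1 CPM (median 1.03). The erythroid list mean was high in cKO 1 (1.14) and cKO 2 (1.35), while cKO 3 (0.306) lay below control 3 (0.478). Lymphocyte genes were higher (median 0.28, 9 of 13 members above 0, camera adjusted p = 0.00316; adjusted p = 0.373 with an estimated correlation), with 3 higher adjusted over the list alone. Cd4 measured 4.97 ± 0.584 and 7.66 ± 0.994 CPM and Cd79b 0.849 ± 0.0244 and 1.30 ± 0.0970 CPM, and the list call was lost without control 2 (median 0.20) or cKO 1 (0.195). With late enamel genes as a covariate the median was 0.44. The lymphocyte list mean in cKO 3 (-0.0117) lay below those of control 1 (0.204) and control 3 (0.0224). Skeletal muscle genes were lower as a list (median -4.05, 19 of 19 members below 0, camera adjusted p = 5.38e-05; adjusted p = 0.545 with an estimated correlation), with none passing either adjustment. Myoglobin, Mb, measured 48.7 CPM in control 1 and between 0.160 and 0.878 CPM in the other mice, and the troponin Tnnt1 2.03 ± 0.529 and 1.21 ± 0.106 CPM. Without control 1 the median was -0.098 and the call was lost, as it was with sex (-0.10) or late enamel genes (-0.46) as a covariate. With a filter of 1 CPM the muscle median was -1.20. Mitochondrially encoded genes were higher as a list in 13 of 13 members (median 0.14, camera adjusted p = 0.0109; adjusted p = 0.628 with an estimated correlation), with none passing either adjustment. The respiratory chain subunits mt-Nd6 and mt-Nd5, whose genes overlap, had log2 fold changes of 0.27 and 0.24. The mitochondrial call was lost without control 1 (median 0.070) and with sex as a covariate (0.065), and without control 3 the median was 0.23.

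The remaining lists were not called. Wnt signalling had a median of 0.019 and a mean of -0.024 (camera adjusted p = 0.301), with the agonist Rspo3 at 0.215 ± 0.0410 and 1.07 ± 0.420 CPM and the transcription factor Tcf7 at 66.0 ± 1.02 and 48.5 ± 4.08 CPM. Adjusted over the list alone, 2 Wnt genes were higher and 5 lower. BMP signalling had a median of 0.095 (camera adjusted p = 0.0836), with 6 higher and 3 lower adjusted over the list alone. The BMP antagonists Grem1 and Nog measured 8.22 ± 3.19 and 41.8 ± 19.2 CPM and 13.3 ± 1.29 and 18.4 ± 2.03 CPM. BMP genes were called higher without control 1 (median 0.14), cKO 1 (0.17) or cKO 3 (0.092), with no filter (0.11) and with sex as a covariate (0.12), all with the preset correlation. With an estimated correlation and all 6 libraries the adjusted p for BMP genes was 0.545. TGF-beta signalling (median 0.10, camera adjusted p = 0.331) had 2 higher and 1 lower adjusted over the list alone, and Inhbb and Ltbp1 had log2 fold changes of 0.80 and 0.67. Its median was 0.060 without control 2, 0.061 without control 3 and 0.037 with late enamel genes as a covariate. FGF signalling (median 0.0022, mean -0.0033, camera adjusted p = 0.950) had none adjusted over the list alone, with Fgf18 at 1.43 (0.92 with late enamel genes as a covariate) and Fgfr3 at 0.55. Notch signalling (median 0.030, mean -0.0090, camera adjusted p = 0.624) had 3 higher adjusted over the list alone, with Dll4 at 0.43 and Notch4 at 0.35. Glycolysis and hypoxia genes (median 0.12, camera adjusted p = 0.460) had 4 higher and 3 lower adjusted over the list alone, with Pgam1 at -0.39 and Ndrg1 at -0.40. Schwann cell and nerve genes (median -0.14, camera adjusted p = 0.217) had 2 lower adjusted over the list alone, with Pmp22 at -0.52 and Tubb3 at -0.71, and were called lower without control 2 (median -0.16) with the preset correlation (adjusted p = 0.661 with an estimated correlation and all 6 libraries). Osteoclast genes (median 0.018, mean -0.12, camera adjusted p = 0.950) had Mmp9 at -1.15 and Ctsk at 0.26. Adipocyte genes (median 0.081, mean -0.16, camera adjusted p = 0.993) had Pnpla2 at 0.33 and Plin4 at -1.09 (-0.36 without control 1), and chondrocyte genes (median -0.012, mean 0.020, camera adjusted p = 0.964) had Col2a1 at 0.65 and Cnmd at 1.14. None of the genes of these 3 lists passed either adjustment.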

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

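Upper-quartile scaling, limma-trend on the deposited normalized signal, the adjusted p of 0.1 and the late enamel covariate were chosen after seeing the data, and the other alternatives before. No paired analysis was possible because no label ties a cKO mouse to a control mouse, although the protocol mentions pairs of samples. The count of 5 genes (4 higher, 1 lower) stayed between 4 and 6 under DESeq2 size factors, library size alone, upper-quartile scaling, no filter, a filter of 1 CPM (which removes Ano3), limma-voom, limma-trend on the deposited signal (4 higher, 2 lower) and a threshold of 1 on the log2 scale. The median log2 change of all genes was 0.00269, 0.00591 and 0.00676 under these 3 scalings. The count was 1333 with DESeq2 (698 higher, 635 lower), 490 at an adjusted p of 0.1 (228 higher, 262 lower), and 0 (0 higher, 0 lower) with sex as a covariate, with late enamel genes as a covariate and at 0.01. At 0.01 DESeq2 called 712. Among the 490 genes, 472 were called by DESeq2, and all 1333 DESeq2 calls had an unadjusted edgeR p under 0.05, while 1897 genes had no adjusted p. In the covariate fits 3073 and 1479 genes had an unadjusted edgeR p under 0.05, and DESeq2 called 1148 and 172. Leaving out 1 library gave 0 to 72 genes, 0 to 28 higher and 0 to 44 lower. The count was 72 without control 2, 8 without cKO 3, 3 without control 3 and 0 without control 1, cKO 1 or cKO 2 (3103, 3278 and 2700 at an unadjusted p under 0.05; 1291, 1105 and 897 by DESeq2). All 5 passed without control 2, Eda2r and Ano3 without cKO 3, and none in the others. Because control 1 was the only male, the fit with sex and the fit without control 1 count as a single check. Fewer libraries and a covariate leave fewer degrees of freedom, but the cause of the changed counts was not tested. Runx2 stayed between -0.62 and -0.45 on the log2 scale and passed only with DESeq2 (-0.52). The other 75 named genes kept their side of the threshold in 1091 of 1189 values, with 34 weaker, 62 stronger (53 of them by DESeq2) and 2 reversed. Those were Igf1, at -0.40 to 0.043, and Igf1r, at -0.13 to 0.043, when 1 library was left out.

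The count of 18 lists was 14 to 20 in all settings except fry (3) and the estimated correlation (0, with 4 lists at an unadjusted p under 0.05). Of 511 list values 408 kept direction and side, 57 were weaker, 9 stronger and 37 reversed. With a filter of 1 CPM the medians that turned were osteoblast -0.0013, ameloblast 0.366 and pericyte 0.0060. With sex as a covariate they were Wnt -0.056, FGF -0.0098, osteoclast -0.0036 and chondrocyte 0.023. With the late enamel covariate they were Wnt -0.018 (called lower with the preset correlation, adjusted p 0.0296, against 0.552 with an estimated correlation and no covariate), Schwann cell 0.197 and osteoclast -0.035. Leaving out 1 library gave medians of -0.0513 to 0.0017 for Wnt, -0.0618 to 0.0392 for FGF, -0.168 to 0.00357 for Schwann cell, -0.238 to 0.0795 for chondrocyte, -0.014 to 0.0649 for Notch, -0.0285 to 0.0539 for osteoblast, -0.0717 to 0.00601 for ameloblast, -0.136 to 0.102 for osteoclast, -0.0515 to 0.0938 for adipocyte and -0.161 to 0.0162 for pericyte. The cause was not tested. At totals of 53525185 to 66694240 counts, depth limits the ratios of Ano3, Svop and Gm18310, whose lower group held 6, 13 and 3 counts.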

Other observations

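All tests in this part were chosen after the results were seen, except the other splits of the samples for the edgeR count of genes and the camera count of lists. DESeq2 called 1333 genes, of which 621 higher and 568 lower met the rule for named genes. The 10 largest in each direction are given beside the 5 edgeR calls. In the simulated data, where 200 genes were changed, DESeq2 made 69 false calls beside 96 and 99 true ones at changes of 1 and 2. There edgeR made 13 false calls beside 87 and 99 true ones. Some of the DESeq2 genes given here may therefore be false calls. Higher in cKO mice were the secreted integrin-like protein Itgbl1 (3.75 ± 0.699 and 21.5 ± 9.81 CPM, SD, n = 3 each; log2 fold change 2.52, DESeq2 adjusted p = 5.21e-11), the BMP antagonist Grem1 (2.35), Dmp1 (2.17), Eda2r (2.23), the ephrin receptor Epha5 (2.01), Cdhr1 (2.40), Dnah6 (2.48), the casein Csn3 (4.44), the macrophage elastase Mmp12 (3.15) and S100a9 (3.51). Lower were the metalloprotease Adamts16 (17.9 ± 2.20 and 2.38 ± 1.43 CPM; log2 fold change -2.91, DESeq2 adjusted p = 1.18e-12), the collagenase Mmp13 (-3.28), the collagen Col6a5 (-2.22), the proteoglycan Podnl1 (-2.28), the contractile protein Cnn1 (-2.86), the secreted neuronal proteins Nptx1 (-2.52), Cbln1 (-3.16) and Scg2 (-3.82), Caln1 (-3.12) and Tmem215 (-2.62). Of these 20 genes edgeR called Eda2r alone. The rule requires groups that do not overlap, so leaving out 1 library could not turn a direction. The DESeq2 call was lost for S100a9 without control 1, control 2 or control 3, for Mmp12 without control 2, for Dnah6 without control 2, control 3, cKO 1 or cKO 3, for Col6a5 without control 1, control 3 or any cKO mouse, and for S100a9 and Col6a5 with sex as a covariate. Dnah6 was at 3.95 without control 1 or with sex as a covariate, and S100a9 at 2.32 without cKO 1. With late enamel genes as a covariate DESeq2 called 12 of the 20, and Mmp13 (-1.66), Scg2 (-2.02), Col6a5 (-1.26), S100a9, Mmp12, Grem1, Dmp1 and Nptx1 were not called, while Cdhr1 was at 1.51, Podnl1 at -1.48 and Dnah6 at 3.81.

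Among genes picked after their values were seen, 6 dentin genes were higher and 3 early enamel genes lower in the cKO mice. The lists chosen beforehand that hold these genes were not called. Odontoblast and mineralization genes had a median of 0.112 (5 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.0836, and 0.373 with an estimated correlation). Bglap and Col1a1 stand instead in the list of osteoblast and Runx2-target genes, with a median of 0.0030 (camera adjusted p = 0.950, and 0.989 with an estimated correlation). Ameloblast genes had a median of -0.0381 (camera adjusted p = 0.791, and 0.949 with an estimated correlation). Dspp, the main dentin phosphoprotein, measured 3422 ± 979 CPM in controls and 9515 ± 3250 CPM in cKO mice (log2 fold change 1.48), with Dmp1 at 2.17, Phex at 1.60, Bglap at 1.29, Col1a1 at 1.08 and Sparc at 0.82. The enamel matrix genes Amelx, Enam and Ambn stood at -1.08, -0.99 and -0.84. The groups did not overlap for any of the 9, and none passed with edgeR over all genes. A smaller epithelial share of the samples would lower all epithelial genes alike and raise all mesenchymal genes alike. The dental mesenchyme progenitor and pulp list, chosen beforehand, had a median of 0.0834 (quartiles -0.133 and 0.301). Because the dentin genes were picked for high values, they were tested against its upper quartile, taken as a fixed value. This test was one-sided and used each edgeR fold change with its standard error, not the two-sided F-test. Adjustment was over all 45 members of the 2 lists that hold the dentin genes. In this one-sided test 0 of the 6 dentin genes passed (adjusted p between 0.0780 and 0.0996). The dental epithelium list, also chosen beforehand, was lower (median -0.342, quartiles -0.565 and -0.0604, 19 of 24 members below 0). The 3 enamel genes were picked for low values, so their lying below that list excludes nothing, and a smaller epithelial share stays open for both sets. A longer piece of incisor, reaching further into later stages, could raise dentin genes and lower early enamel genes. With late enamel genes as a covariate the median change in the stated direction was 1.08 before and 1.08 after, and 9 of 9 genes kept their direction, but fry, limma's rotation test, gave a p of 0.122 (0.122 adjusted over the 4 covariate tests here). Control 2 had late enamel genes as high as the cKO mice without the dentin and early enamel differences. Its dentin score was 0.0337 against 0.963 to 1.87 in cKO mice, and its early enamel score -0.106 against -0.534 to -1.57. Some other genes lower in cKO mice, such as Gli1 and Mmp13, were nearer the cKO values in control 2 than in the other controls. Control 2 is 1 library. The length of the piece, a smaller epithelial share and an effect of the genotype therefore cannot be told apart for these 9 genes.

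The hedgehog list was lower in cKO mice, and the Gli1-CreERT2 allele is a candidate cause, since such alleles are commonly placed in the Gli1 gene itself and can lower its reading. The labels do not describe the allele. Without Gli1 the list had a median of -0.195, 12 of 16 members were lower and camera gave an unadjusted p of 0.00498, which argues against the Gli1 reading alone; an effect of a lower Gli1 dose on the other genes was not tested. A longer piece of incisor stays open: with late enamel genes as a covariate the median decrease went from 0.282 to 0.18, 13 of 17 genes kept their direction and camera still called the list (adjusted p 0.0132), but 63.8% of the decrease was left and fry gave a p of 0.113 (adjusted 0.122), so it cannot be told apart from the genotype for this list. Both camera values use the preset correlation. With an estimated correlation the hedgehog list was not called (adjusted p = 0.290, the highest over its alternatives). Its member Shh stands also in the dental epithelium list and measured 291 ± 54.9 and 166 ± 44.3 CPM (log2 fold change -0.81, edgeR adjusted p = 0.131). A smaller epithelial share of the samples was not tested for the hedgehog list and stays open too.

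The macrophage list was higher in cKO mice in all 19 members. All 19 are detected in the controls as well, and the list's most abundant genes include Lyz2, at 141 ± 18.6 and 216 ± 14.9 CPM, and Csf1r, at 95.4 ± 17.7 and 146 ± 15.4 CPM. A longer piece of incisor would leave little of the difference once late enamel genes are a covariate, yet the median went from 0.558 to 0.476, with 19 of 19 genes above 0 and a median SE per gene of 0.15. Camera still called the list, and fry gave a p of 0.0361, which is 0.0722 adjusted over the 4 tests. That does not pass, and the covariate parts from genotype mainly through control 2, which is 1 library. Blood or marrow carried over would leave little once neutrophil transcripts are a covariate, and the median was 0.616 (19 of 19 above 0, with a fry p of 0.00774, adjusted 0.0309); cKO 3, with neutrophil genes at the control level, had the highest macrophage score (0.662). A smaller share of the main tissue would raise other cell types alike. The macrophage median exceeded that of Schwann cell and nerve genes by 0.695. Its lower quartile (0.496) lay above the upper quartiles of Schwann cell (0.361) and endothelial genes (0.315). The macrophage list was taken up after its large shift was seen, so its lying above weaker lists excludes nothing. The neutrophil covariate sets cKO 1 and cKO 2 apart, so that fit rests mainly on cKO 3. In cKO 3 the values argue against blood or marrow carried over, but it is 1 library. None of the 3 explanations is excluded as the whole cause. More macrophages, or more active ones, in cKO tissue may be a biological explanation, as a hypothesis only, which counting macrophages in tissue sections would decide and these data do not. The list was not called by camera with an estimated correlation (adjusted p = 0.290, the highest over its alternatives), and other tissue carried over was not tested.

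The 6 libraries can be split into groups of 3 in 10 ways, too few for a share under 0.05. The real split gave 5 genes by edgeR, and the highest of the others gave 2. It gave 18 lists by camera, and the others gave 4 to 15, so camera with the preset correlation called lists in every mixed split too. It gave 1333 genes by DESeq2, and the highest of the others 111. It gave 3325 genes at an unadjusted edgeR p under 0.05, and the highest of the others 1552. For each of the 4 counts, 1 of the 10 splits, the real one, gave a result as large.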
